A study of Homo sapiens with 2 samples.

How the data were processed

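The series holds 1 ChIP-seq library of MYC and 1 input library of sonicated chromatin, both from TET21 cells that ectopically express full-length MYC. Per the labels' protocols, the cells received 1 µg/mL doxycycline for 7 days and were fixed with 1% formaldehyde for 10 min. The chromatin was immunoprecipitated overnight with 2 µg of a rabbit polyclonal antibody against MYC made in the submitters' laboratory. The labels do not say whether the antibody separates ectopic from endogenous MYC. RNA-seq of MYC deletion mutants, named in the design text, was not analysed here.

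The file analysed here is the authors' list of 17659 peaks for the ChIP library, in narrowPeak layout, with peak names in the style of MACS. The submitters' processing notes name GRCh37, STAR 2.5.2a, SAMtools 1.3, Picard 2.7.1 and MACS2 2.1.0, with no role or order, and bedtools. The authors' deposited score is a whole number that equals 10 times the −log10 q, rounded down, in 100.0% of peaks. The authors' deposited fold (a ratio) is the enrichment at the peak over the caller's local background. The authors' deposited −log10 p and −log10 q values, which the layout assigns to the columns after the fold, come from the peak caller. The weakest peak has a −log10 q of 1.307 (a q-value of 0.0493) and a −log10 p of 4.005. The summit position is given as a distance in bp from the peak's start. The list had been filtered by a rule not given in the sources used here: peak numbers run to 17679 and 20 are missing. Of these, 7 fall between the last peak of chromosome 9 and the first of chromosome X in the list's order, and 13 fall elsewhere. Coordinates are GRCh37 and are given 1-based.

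The gene table at hand (RefSeq, GRCh38.p14) is on another build, so its coordinates were not combined with the peaks. It was used only to count protein-coding genes per chromosome (19974 on chromosomes 1 to 22 and X). No genome sequence or GRCh37 annotation was used here. For that reason 6 of the 8 results fixed before the data were examined were not computed: the share of peaks at transcription start sites, the share of genes with a promoter peak, the gene lists, the E-box and other motif counts, and the contrast of promoter with distal peaks. The rule for named genes could not be applied. In its place the peaks with the highest −log10 p are named by position, and every peak of the contig GL000220.1, a choice made after the values were seen. From the fixed gene lists, only the olfactory receptors (390 coding genes) and keratin-associated proteins (94 coding genes) were used, as genes to leave out of a chromosome's gene count.

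Pileup and background were recovered from each peak's fold and −log10 p. MACS2 defines the fold as (pileup + 1) / (background + 1) and p as the Poisson probability of more than the pileup given the background, so every whole pileup from 3 to 699 was tried and the one that gave the deposited −log10 p was kept. A whole pileup matched within 0.001 for 100.0% of peaks, with a largest miss of 0.000221. Counting the pileup itself in the Poisson tail matched 0.085% of peaks, and shuffling p between peaks matched 0.991%. On 2991 simulated peaks the procedure recovered 100.0%. The pileup is the number of ChIP fragments over the summit. The lowest common background, 0.6832 fragments, was shared by 1761 peaks within 0.0003, and this tolerance defines the floor throughout. Other backgrounds lay on steps of 0.6599, 0.09371 and 0.00937, the spacing that whole input fragments give when counted over 1 fragment length, over 1 kb and over 10 kb and scaled to the ChIP library. The floor and the first 2 steps took in 80.4% of peaks within 0.0003, and all 3 steps 100.0%, although the finest step takes in 6.4% of any values by chance. The steps give a fragment length of 142.0 bp, and the narrowest peak was 142 bp. The background is therefore read here as the caller's local estimate from the input with a genome-wide floor. The step puts the input at 1.515 times the depth of the ChIP library, if the caller scaled the deeper library down. If the caller used an effective genome of 2700000000 bp, which no label states, the floor corresponds to 12.99 M ChIP and 19.68 M input fragments. The depth is otherwise unknown.

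Peaks per Mb were computed over the span from the first to the last peak of a chromosome, since assembled lengths of GRCh37 were not used here, and peaks per 100 coding genes over the RefSeq counts, with exact Poisson 95% intervals. Shares have Wilson 95% intervals. Geometric means, medians and their ratios have bootstrap 95% intervals over peaks (2000 draws). The Poisson and Wilson intervals cover counting error within 1 library, and the bootstrap intervals cover the spread among its peaks. Intervals on numbers, shares and averages of peaks treat peaks as independent, although peaks were crowded, so they may be too narrow. Sequenced fragments without molecular identifiers are not independent molecules. Relations over chromosomes were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 3 relations. Each of 23 chromosomes was scanned for 1 change in mean log2 background, on peaks at least 20 kb apart, with 2000 permutations of the peaks' order and Benjamini-Hochberg adjustment, and 500 residual bootstraps for the position. A chromosome was divided at its step only where the adjusted p was under 0.05 and the step was over 0.3 on the log2 scale; otherwise it was taken whole. A whole chromosome or divided part counted as having a higher background when its mean log2 value lay more than 0.3 above the median chromosome. The scan found 99.0% of simulated steps of 0.5 on the log2 scale among 300 peaks and called 8.0% of simulated chromosomes of 300 peaks with no step. Crowding was compared with 100 random placements within each chromosome's span and with 100 sets of peaks each shifted at random by up to 50 kb. With 1 ChIP library there was no replicate error, and no test between conditions was made. The fold adds 1 to pileup and background, so at equal enrichment it is lower where fewer fragments are counted. The background is the highest of several estimates and cannot fall below the floor, so ratios of background understate differences in the input. Alternatives were the peaks at or above the median and the upper quartile of −log10 p, other rankings, distances and measures, and random thinning of pileups. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.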

Results

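MYC is a basic helix-loop-helix leucine zipper transcription factor that binds DNA as a dimer with MAX. Its chromatin binding was profiled by ChIP-seq in TET21 cells, a clone of the human neuroblastoma line SH-EP that carries a doxycycline-repressible MYCN transgene. The cells expressed full-length MYC and had been in doxycycline for 7 days. The stated purpose of the experiment was to locate MYC on the genome, beside transcriptomes of cells with MYC deletion mutants that were not analysed here. There was 1 ChIP library and 1 input library, so no value below has a replicate error. The intervals cover only counting error or the spread among peaks.

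MYC was called at 17659 sites, of which 17632 lay on chromosomes 1 to 22 and X. The sites were narrow, with a median width of 226 bp (quartiles 171 and 313 bp), and together covered 4725 kb. Only 1204 peaks (6.82%) were wider than 500 bp and 48 were wider than 1000 bp. The median fold over the local background was 6.4, with quartiles of 5.17 and 8.38. A fold of 10 or more was reached by 2722 peaks (15.41%), a fold of 20 or more by 253 (1.43%) and a fold of 30 or more by 38. The median peak rested on a pileup of 13 ChIP fragments at its summit against a background of 1.13 expected fragments, and the 5th percentile of the pileup was 8 fragments. The weakest peaks called at the lowest background had a pileup of 5 and a fold of 3.56. Where the background equalled 4 scaled input fragments, the weakest peak called had a pileup of 10 and a fold of 3.02. At these backgrounds, sites with fewer fragments did not pass the caller's q-value threshold, while lower folds were called at higher backgrounds.

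The strongest site was on chromosome 7 at 4681417 to 4682026, where 115 fragments (95% Poisson interval 94.9 to 138.0) lay over a background of 0.937, a fold of 59.88 and a −log10 p of 194.21. The next by significance were both on chromosome 17, at 42147906 to 42148413 with a fold of 43.96 and at 75084615 to 75084968 with a fold of 37.59. A peak on chromosome 5 at 170815246 to 170815763 ranked 4 by significance and 2 by fold, at 48.21. The other 6 of the 10 most significant peaks were on chromosome 7 (807264 to 808423, fold 34.57, and 766045 to 766393, fold 39.03), chromosome 17 (61850751 to 61851857, fold 40.09, and 49230663 to 49231317, fold 32.75), chromosome 10 (103892680 to 103893662, fold 38.06) and chromosome 1 (156024147 to 156024797, fold 33.50). Their pileups ranged from 79 to 102 fragments. The 95% Poisson intervals of these 6 counts overlap, so the order of these 6 pileups is uncertain, but differences between them were not tested. These sites were not matched to genes here, since no GRCh37 annotation was used.

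Chromosomes with more protein-coding genes held more MYC peaks. Over 23 chromosomes the number of peaks correlated with the number of protein-coding genes (Pearson r = 0.929, Spearman rho = 0.912, permutation p = 1.0e-05 for each, the smallest that 100000 permutations can give, and 1.5e-05 after adjustment over 3 relations). Without chromosomes 1 and 21, the farthest from the median gene count, r was 0.860. The correlation with the length spanned by peaks was lower (r = 0.631, permutation p = 0.0012, adjusted p = 0.0012; rho = 0.531, adjusted p = 0.01) and fell to r = 0.413 (permutation p = 0.063) without chromosomes 1 and 2, so the Pearson correlation rests in part on those. Peaks per Mb and coding genes per Mb correlated with r = 0.949 (rho = 0.930, adjusted p = 1.5e-05 for each by permutation), and r was 0.902 without chromosomes 19 and 17. Both rates are divided by the same span, which can by itself raise this correlation, and the permutation does not allow for that. Gene-dense chromosome 19 had the highest density, 17.81 peaks per Mb (95% interval 16.74 to 18.92), followed by chromosome 17 with 14.79 and chromosome 22 with 12.36. Chromosome X had the lowest, 2.01 per Mb (1.79 to 2.24), and chromosome 4 had 3.41.

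**Figure D1:**
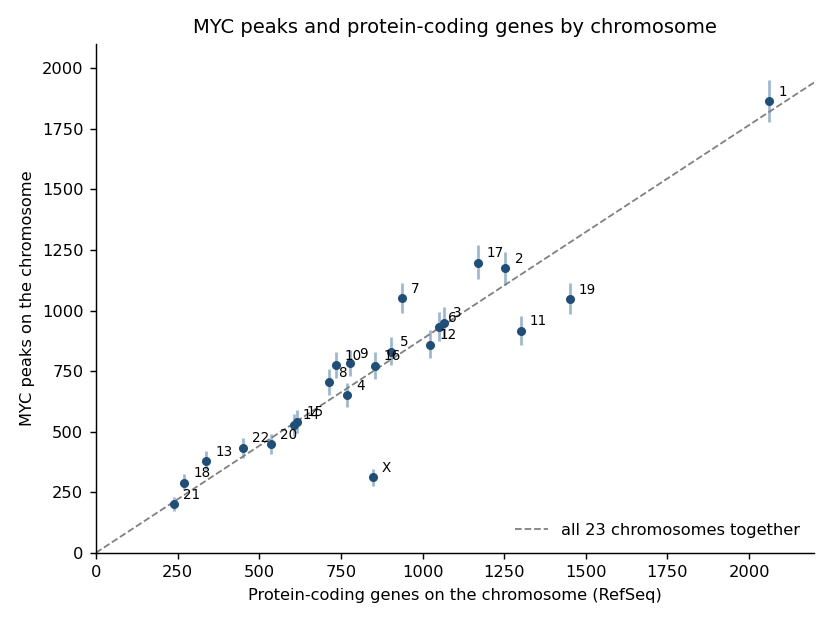
Number of MYC peaks (vertical axis) against the number of protein-coding genes (horizontal axis) on chromosomes 1 to 22 and X; bars are exact Poisson 95% intervals and the dashed line is the rate over all 23 chromosomes, 88.3 peaks per 100 coding genes. Chromosome X lies far below the line at 36.7 and chromosome 7 above it at 111.9.

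Per 100 coding genes, chromosomes 1 to 22 held between 70.5 peaks (chromosome 11) and 112.1 peaks (chromosome 13). Chromosome 7 held 111.9 (105.3 to 118.9), chromosome 18 held 107.4 and chromosome 10 held 105.4. Chromosome 19 was among the lowest at 72.2 (67.9 to 76.7), although it was the densest per Mb. Chromosome X held 36.7 (32.7 to 41), below every other chromosome. Olfactory receptor and keratin-associated protein genes, large tissue-restricted families, had been fixed as controls. Leaving them out of the gene count raised chromosome 11 from 70.5 to 81.9 and chromosome 21 from 83.7 to 105.3. Chromosome 19 changed from 72.2 to 73.2 and X stayed at 36.7. Leaving them out could hardly move these 2 values. Chromosome 19 has 20 olfactory receptors among 1451 coding genes, X has 1 among 848, and neither has keratin-associated genes.

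MYC sites were crowded. Another peak lay within 1 kb of 5769 peaks (32.7%), against a median of 322.5 (1.8%) in 100 random placements along the same chromosomes. Shifting each peak at random by up to 50 kb, which keeps the regional density, gave 966.5 (5.5%), and none of 100 shifted sets exceeded 1065. At 50 kb, the size of the largest shift, the shifted sets keep most neighbours by construction, with a median of 13094.5 (74.3%) and a maximum of 13259 against the observed 13322 (75.6%). Joining peaks no more than 1 kb apart gave 14470 bound regions: 11863 of 1 peak, 2149 of 2 peaks and 458 of 3 or more. The closest neighbours were 52 bp apart, and whether such peaks are separate binding sites was not tested. The median best fold was 6.42 (95% interval 6.39 to 6.47) in regions of 1 peak and 9.24 (8.91 to 9.76) in regions of 3 or more, but the best of as many single peaks drawn at random had a median of 9.11, within the interval of the regions of 3 or more.

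The region with the most peaks was on chromosome 17 at 4869627 to 4872834, where 7 peaks lay within 3208 bp, the best with a fold of 7.05. Of the 3 regions with 6 peaks, all on chromosome 17, that at 79826070 to 79829589 was the strongest, with a best fold of 26.01. The densest 1-Mb windows were 79 to 80 Mb on chromosome 17 with 64 peaks, 1 to 2 Mb on chromosome 19 with 61, 7 to 8 Mb on chromosome 17 with 56 and 65 to 66 Mb on chromosome 11 with 53. Windows with 20 or more peaks numbered 174 and held 27.5% of the peaks. In contrast, 31 stretches of over 5 Mb had no peak. The longest, 30.11 Mb on chromosome 9 and 22.01 Mb on chromosome 1, lie across the centromeric regions, which are known to map poorly. On chromosome X a stretch of 13.62 Mb, from 86983366 to 100603635, held none.

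The local background under the peaks, read here as the caller's estimate from the input, was not even along the genome. The scan, which fits 1 change of mean per chromosome, placed a rise on chromosome 1. It ran from a geometric mean of 1.09 to 1.59 fragments between summits at 117635990 and 117664478 (95% bootstrap range of the step 115969036 to 142618896, which includes the peak-free centromeric stretch). On chromosome 17 the fitted rise was from 1.1 to 1.61 between 43449213 and 43661755 (range 42907783 to 45307326). Both steps had a permutation p of 0.0005, the smallest that 2000 permutations can give, and an adjusted p of 0.0057 over 23 chromosomes. These p-values test for any uneven background along a chromosome, and a gradual rise or several steps were not compared with 1 step. Chromosome 7 had a high background along its length (geometric mean 1.48 over peaks at least 20 kb apart, against 0.953 to 1.1 on the chromosomes other than 1, 7 and 17). Chromosome X showed a smaller step down, from 1.17 to 0.920 near 15.7 Mb, which the scan places anywhere from 2270310 to 41192827 (adjusted permutation p = 0.038).

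**Figure D2:**
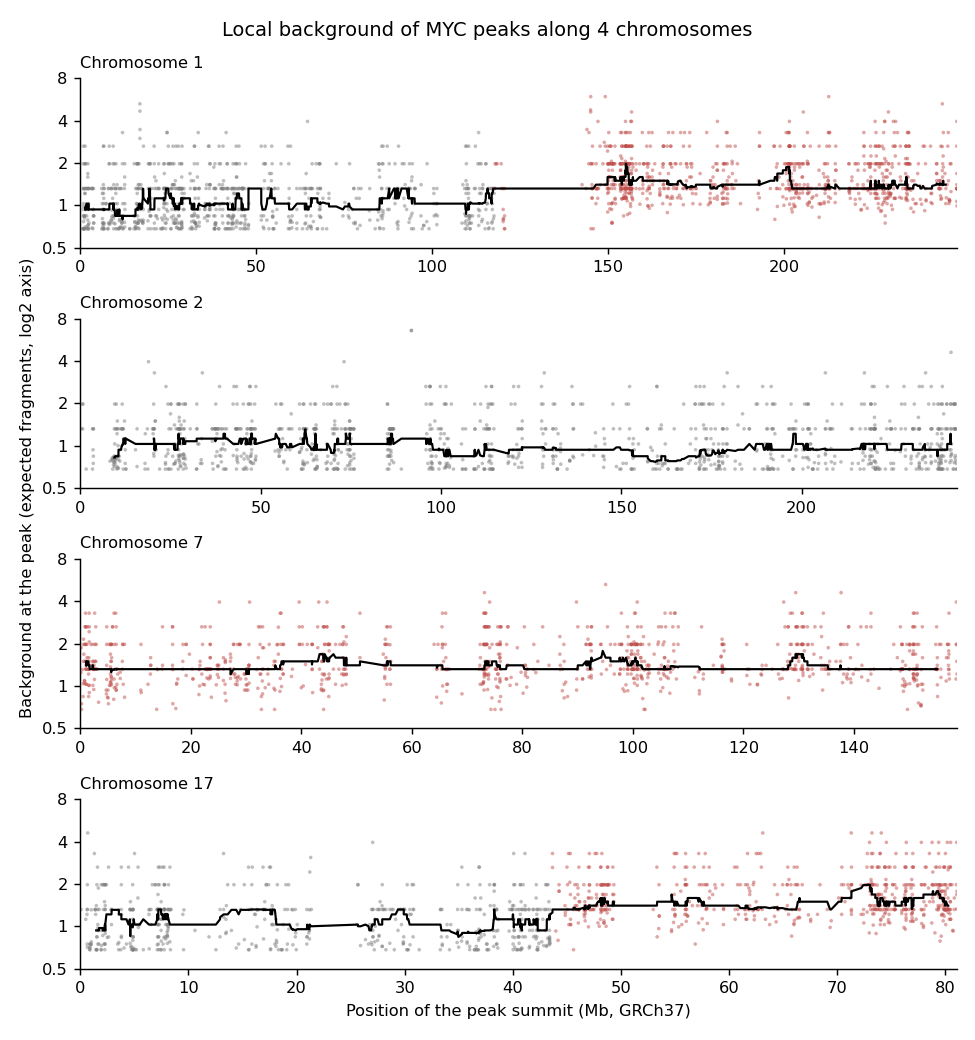
Background at each peak (vertical axis, expected fragments at the summit, log2 axis) against summit position (horizontal axis, Mb, GRCh37) on chromosomes 1, 2, 7 and 17; points are peaks, red where the segment's mean was more than 0.3 log2 units above the median chromosome, and the line is a running median of 51 peaks. In the fit of 1 change per chromosome, chromosomes 1 and 17 rise from geometric means of 1.09 and 1.1 to 1.59 and 1.61, chromosome 7 is high throughout, and chromosome 2 (1.07) shows no step.

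The peaks on distal chromosome 1 (967 peaks), chromosome 7 (1050) and distal chromosome 17 (619) together made up 14.95% of those on chromosomes 1 to 22 and X. The background of the peaks in these segments was 1.46 times that elsewhere (95% interval 1.44 to 1.49) and only 0.57% of them sat at the genome-wide floor, against 11.64% elsewhere. The segments were picked by their mean log2 background, so both differences follow in part from that choice, which the interval leaves out. The ChIP pileup of these peaks was also higher, by 1.26 times (1.24 to 1.29), and their fold was 1.01 times that elsewhere (0.990 to 1.02), an interval that includes no difference. The 897 peaks of chromosome 1 before its step had a background of 1.09 and a median fold of 6.47, and the 579 of chromosome 17 before its step had 1.1 and 6.51. A pileup of 40 or more was reached by 5.33 peaks per 100 coding genes on chromosome 7, 4.96 on chromosome 17 and 3.15 on chromosome 1, and by at most 2.09 on any other chromosome. These rates are for whole chromosomes and not for the segments. Strong peaks on chromosomes 1 and 17 also lay before the steps. Of 35 peaks with a fold of 20 or more on chromosome 17, 16 lay after its step, and of 26 on chromosome 1, 16 did.

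The share of these segments among the strongest MYC sites depended on the measure used to rank them. They held 26% of the 500 most significant peaks (Wilson 95% interval 22.3 to 30), 19.6% of the 500 with the highest fold (16.4 to 23.3) and 32.4% of the 500 with the highest pileup (28.4 to 36.6). All exceeded their 15.0% of all peaks. By fold, the lower ends of the intervals for the top 100 (22%, 15.0 to 31.1) and the top 2000 (16.6%, 15.0 to 18.3) lay close to that share. Among the 100 most significant, 12 were on chromosome 7, 11 on distal chromosome 17 and 8 on distal chromosome 1.

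**Figure D3:**
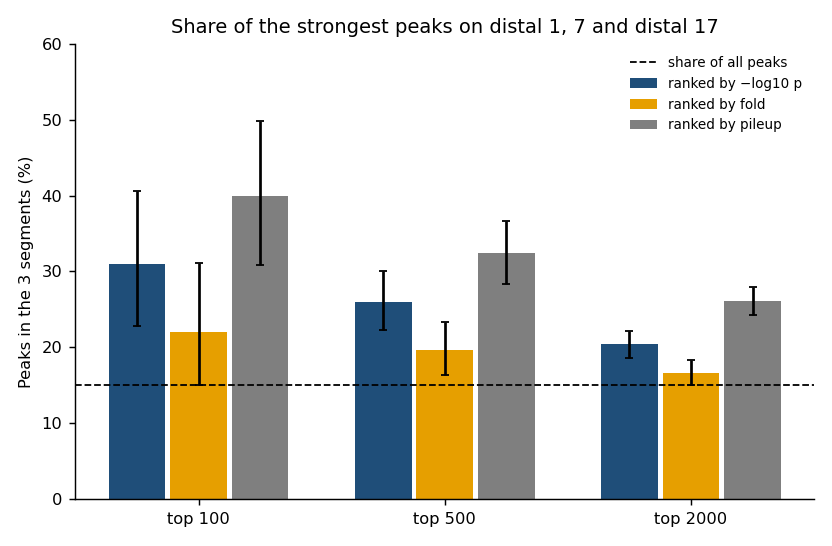
Percentage of the strongest 100, 500 and 2000 peaks that lay on distal chromosome 1, chromosome 7 or distal chromosome 17 (vertical axis), ranked by −log10 p, fold or pileup; error bars are Wilson 95% intervals and the dashed line marks these segments' 15.0% of all peaks. For each list the share was highest by pileup and lowest by fold, 32.4% and 19.6% in the top 500.

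Outside the assembled chromosomes, 26 peaks lay on 9 unplaced contigs and 1 on chromosome Y. GL000220.1, an unplaced contig known to carry ribosomal RNA gene sequence, held 6 peaks. Of these, 4 had backgrounds of 79.8 to 83.8 fragments, 117.8 times the genome-wide floor at their median, whereas no peak on chromosomes 1 to 22 and X exceeded 6.60. The widest, at 117832 to 119297, had a pileup of 210 (182.6 to 240.4) over a background of 79.9, a fold of 2.61 and a −log10 p of 33.44. Its neighbour at 119609 to 119993 had a fold of 2.23, and the peaks at 134250 to 134391 and 142494 to 142704 had folds of 1.59 and 1.69. These are the 4 lowest folds of the list, since the lowest on chromosomes 1 to 22 and X was 2.63. The other peaks of this contig, at 6980 to 7505 and 7601 to 8370, had folds of 10.66 and 8.79 over backgrounds of 5.94 and 4.69. GL000195.1 held 8 peaks and GL000205.1 held 5, with folds of up to 10.55 and 8.36.

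**Figure D4:**
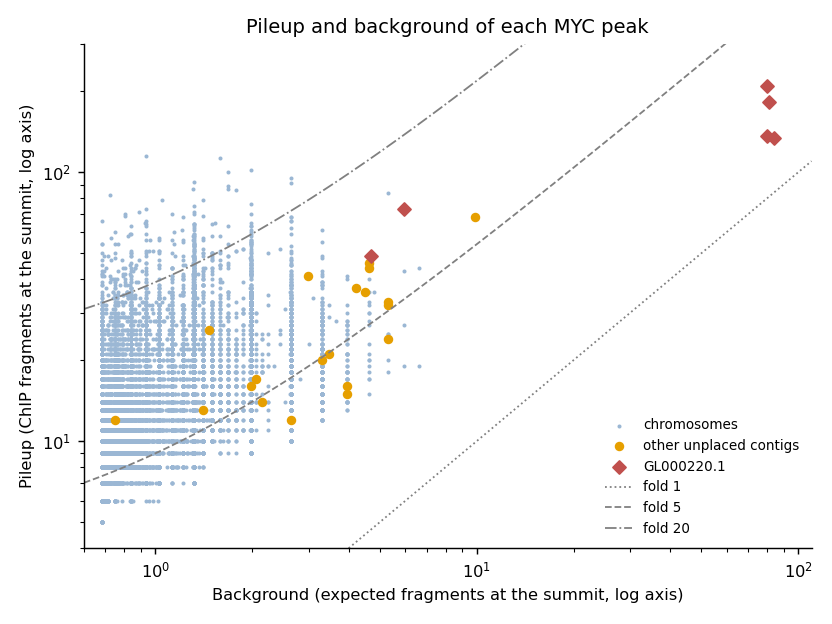
Pileup (vertical axis, ChIP fragments at the summit, log axis) against background (horizontal axis, expected fragments at the summit, log axis) for all 17659 peaks; lines mark folds of 1, 5 and 20, the fold being (pileup + 1) / (background + 1). The 4 peaks of GL000220.1 with backgrounds near 80.5 stand apart from all others, between the lines of fold 1 and 5.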

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

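Of 8 results chosen before the data were examined, 2 could be computed, the number of peaks and the peaks per Mb; the tests on crowding, correlation, background, top lists and chromosome 7 were chosen after seeing the data. The settings meant for the other 6, on start sites, promoters, gene lists and motifs, were not run because they need a GRCh37 annotation or sequence. Of 26 alternatives, 12 left a value within its 95% interval or a count within 1.5 times, and 14 moved it. The interval for the correlation came from a bootstrap over chromosomes. None of the background ratios, segment shares or correlations reversed its direction. Keeping peaks at or above the median −log10 p left 8874 peaks, and at or above the upper quartile 4431. At the median, the density fell from 17.81 to 9.12 per Mb on chromosome 19, from 6.62 to 3.71 on chromosome 7 and from 2.01 to 0.84 on chromosome X. Peaks with a neighbour within 1 kb fell to 1575. Using fewer peaks causes a fall by construction, but the fall was proportionally larger on X than on 7 or 19, which was not tested. The background of the 3 segments over that elsewhere was 1.42 for peaks over 50 kb from any other and 1.642 at the 25th percentile, and the cause was not tested. The segments' share of strong peaks was 19.6% by fold and 32.4% by pileup in the top 500, and 31% and 20.4% by significance in the top 100 and 2000. Thinning chromosome 7 by 1.5 and 2.0 lowered its peaks per 100 coding genes to 103.6 and 92.5, since fewer fragments were counted. The correlation of peaks with coding genes stayed between 0.860 and 0.912 under its 4 alternatives. With 1 library per kind, no replicate could be left out. No peak with a pileup under 5 was called, which limits what this depth can show.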

Other observations

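The tests on fold, on peaks at the floor, on the fold ranking and on raised or thinned pileups of the segments were chosen after the result was seen; those on weak isolated peaks, on thinning chromosome 7 and on chromosome X were written before theirs, but after the peak list had been examined.

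Chromosomes also differed in sites per gene where the background was ordinary. Chromosomes 13, 18 and 10, which are not gene-dense, held 112.1, 107.4 and 105.4 peaks per 100 coding genes, with backgrounds of 1.04 fragments each, close to the 1.07 outside distal 1, 7 and distal 17. Chromosomes 19 and 11, with the most coding genes after chromosome 1, held 72.2 and 70.5, or 73.2 and 81.9 without olfactory receptor and keratin-associated genes. This did not follow gene density throughout, since chromosome 4, with 4.04 coding genes per Mb, held 84.4 and chromosome 22, with 12.88, held 96.0, and the relation was not tested. The median fold was 6.51 on chromosome 19 and 6.28 on chromosome 11, against 6.4 over the whole list.

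The background step fitted on distal chromosome 1 and distal chromosome 17 and the high background of chromosome 7 have the form of copy-number gains, and gains of 17q, 7 and 1q are common in neuroblastoma. The scan could fit only 1 step per chromosome, so the step form is not evidence of a gain. Strong or crowded peaks that raise the input locally are argued against as the only source: among weak peaks more than 50 kb from any other, the background in the segments was still 1.416 times that elsewhere (95% interval 1.35 to 1.49; 259 and 2001 peaks). Strong or crowded peaks alone would not raise it at such sites. These weak peaks were among those by which the segments were picked, so the size of the ratio follows in part from that choice. The share of peaks at the floor in the segments was 0.049 times that elsewhere. That share could not test whether a few sites with very high input made the pattern, since the segments were picked by their mean log2 background. The fold did not decide on a gain: its median in the segments was 0.997 times that elsewhere (0.982 to 1.01), 6.38 against 6.4, while the other peaks give a median of 5.24 when only their background is raised by 1.464 and they are called again, and of 7.36 when their pileup is raised too, a value that newly listed weak sites would lower. Pileup rose by 1.264 times, less than the background. Thinning the segments' peaks by 1.464 left a fold of 0.904 times that elsewhere. Neither value decides on a gain with equal occupancy per copy. The smallest pileup called was 5 at the floor and 10 where the background equalled 4 scaled input fragments. Which weak peaks are listed, and so the average pileup, therefore depends on the background. The thinning was simulated at an assumed factor and only lowered the pileups of summits already chosen. It could not pick new summits or add peaks, as calling a shallower library could. A gain may stand only as a hypothesis that no test here decides.

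Whether the segments' share of the strongest MYC sites follows the number of fragments or occupancy was not decided. Ranked by fold, their share of the top 500 was 19.6% against 26% by significance and 15.0% of all peaks, and its interval of 16.4 to 23.3 does not place it nearer to either. By fold, the segments held 22% of the top 100 (15.0 to 31.1) and 16.6% of the top 2000 (15.0 to 18.3). The lower ends of both intervals lie close to the share of all peaks, and the fold itself rises with the number of fragments. For the number of sites on chromosome 7, thinning by 1.5 left 103.6 peaks per 100 coding genes, above the median of 88.9 on the chromosomes other than 1, 7 and 17. This could not exclude an effect of the number of fragments, because the bound was the highest of those, 112.1 on chromosome 13, and chromosome 7 was already below it at 111.9 before thinning.

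Chromosome X held 36.7 peaks per 100 coding genes against 90.6 on chromosomes 1 to 22, and 22.5% of its peaks sat at the floor against 9.8%. A loss of weak sites only is argued against: peaks with a fold of 10 or more per 100 coding genes were 0.372 times the median of chromosomes 1 to 22 (95% interval 0.269 to 0.5; 43 peaks on X), although such folds also become rarer with fewer fragments. The interval covers counting error on X only and not the spread among chromosomes 1 to 22, and its upper end reaches the bound of 0.5 written beforehand. The rate was 5.07 on X, against 9.68 on chromosome 11, the lowest of chromosomes 1 to 22. Fewer fragments per site on X may still contribute: keeping each fragment of chromosomes 1 to 22 with a probability of 0.5 left 68.5 peaks per 100 coding genes, over the bound of 60 written beforehand as excluding it. That bound was set aside after the value was seen, because the probability is assumed and not measured, and one of 0.25 left 27.2, fewer than X holds. Which X-linked genes are active was not tested.

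The missing peak numbers show between which listed peaks the filtered ones lay. They include 2 in the 30.11 Mb stretch of chromosome 9 and 1 in the 22.01 Mb stretch of chromosome 1 that hold no listed peak.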
